A study of Homo sapiens with 8 samples.

How the data were processed

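Circular RNAs (circRNAs), which form when the end of an exon is joined back to the start of the same or an earlier exon, were counted in total RNA of A549 and MCF-7 cells. A549 is a human lung adenocarcinoma line and MCF-7 a human oestrogen receptor positive breast cancer line. Per the labels' protocols, A549 cells grew in DMEM and MCF-7 cells in RPMI-1640. The labels state that 100000 A549 or 200000 MCF-7 cells were seeded, and that hypoxia began 24 h later and lasted 48 h at 0.5% oxygen. Per the labels, ribosomal RNA was depleted before library preparation and sequencing on an Illumina NextSeq. The 8 libraries form 4 groups of 2, normoxia and hypoxia in each line. The series text mentions a smaller number of samples than the sample labels, and the sample labels were followed. Nothing in the labels says whether the replicates are separate cultures, so the p-values measure only the spread between the samples given. Medium, seeding density and line differ together, so the comparison between lines cannot separate them.

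The authors deposited, per the file headers, 1 table of raw counts per library. Each entry is a circRNA with its host gene, its chromosome, start, end and strand, and the count in that library. The values are whole numbers, and a count stands for sequencing reads across the junction that closes the circle. Per the submitters' processing notes, FastQC 0.11.5, STAR 2.4.5a, Bowtie2 and HTSeq 0.6.1 were used with the builds hg38 and GRCh38. The program that detected the circles is not given in the sources used here. The tables list the same 12006 circRNAs, of which 2159 had 0 counts in every library and 9847 had at least 1. In each of the 8 libraries fewer circRNAs had exactly 1 count than exactly 2 (180 against 326 in A549 hypoxia replicate 1), and 0 circRNAs had 1 count over all libraries together. A minimum of read support before the tables were made is not given in the sources used here, and was not excluded; with one, a count of 0 or 1 and the number detected would refer to circRNAs past that minimum.

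Coordinates were taken as the files give them, on GRCh38, and compared with GENCODE release 44. Both ends lay at exon ends of 1 annotated transcript for 85.5% of the listed circRNAs, both ends lay at exon ends but of different transcripts for 1.69%, 1 end did for 9.07%, and no end did for 3.75%. The genome sequence had AG before the start and GT after the end, the usual splice signals, for 11970 circRNAs (99.7%). Of 4395 host gene names, 4312 matched a current symbol, and 469 circRNAs were given a newer symbol. A host was missing for 315 circRNAs, which held 1.87% of all counts, and the annotation placed 217 of them. A further 24 circRNAs carried a calendar date in place of a gene symbol and were all placed by position. A host gene here is the gene whose exons the circle holds; its linear mRNA was not measured, so nothing is said about host gene expression. circRNAs are identified by position, and several circles of 1 host share exons.

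Library totals ran from 13402 to 35231 counts, so that 3 counts, the number that a count of 0 allows, correspond to 0.852 to 2.24 per 10000 counts of a library. The reads carry no molecular identifiers, so these floors and the 95% intervals (exact binomial for shares, exact conditional for ratios of counts) cover counting error only. Levels are given as counts per 10000 scaled circRNA counts, with scaling by edgeR's trimmed mean of M-values (TMM). A level is therefore a share of circRNA counts and not an amount per cell. Where a group had 0 counts, the fold is a lower bound against 3 counts over the 2 libraries of that group. This bound takes the counts of the other group as observed and leaves out their counting error, so it is not a 95% limit. Where a group had 1 to 3 counts, the ratio is given with its exact interval.

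Differences were tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit) in R 4.3.3. All 8 libraries entered 1 fit with a mean per group, which leaves 4 residual degrees of freedom. A circRNA entered the fit with 5 or more counts in at least 2 libraries (1895 circRNAs). It was tested in a comparison with 5 or more counts in at least 2 libraries of that comparison. Tested numbers were 694 in A549, 1527 in MCF-7, 989 between the lines in normoxia, and 470 in both lines for the difference and the mean of the hypoxia effects. Adjusted p-values are Benjamini-Hochberg values of this edgeR test within a comparison, with a threshold of 0.05. Standard errors of log2 fold changes are approximate, taken from the fold change and the square root of its F statistic. Counts were also summed per host gene and tested in the same way. Numbers of detected circRNAs were compared with two-sided exact permutation tests, which cannot go below p = 0.333 within a line or 0.0556 over both lines. Each library was also thinned at random to 13402 circRNA counts, which equalises that total and not the number of sequenced reads or distinct molecules.

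The 12 lists of host genes and the naming rule were written before the data were examined. The restriction to annotated exon ends among the alternatives, and some tests of explanations, were chosen after the data were seen and are marked where they are given. They were HIF target genes, glycolysis and glucose storage, collagen modification and matrix, chromatin modifiers, splicing factors and RNA-binding proteins, cell cycle and DNA replication, endoplasmic reticulum stress and protein folding, ubiquitin ligases and proteolysis, abundant circRNA host genes, A549 lineage and NRF2 pathway, MCF-7 luminal and amplified genes, and fibroblast and blood cell genes. A list with at least 5 tested circRNAs was tested with camera of limma 3.58.1 (preset correlation 0.01), with camera at an estimated correlation, and with the rotation test fry. Shorter lists are given as values. Each circRNA of a list was also called with its p-value adjusted over the list alone. Per comparison, the rule named the 10 highest and 10 lowest log2 fold changes among circRNAs that passed and whose groups did not overlap. Where fewer passed, circRNAs with the smallest unadjusted p filled the places. It also named list members that passed, the most abundant member of each list, and the 10 most abundant circRNAs. The text prints those at the top of these rankings. Any other circRNA is marked as chosen after its values were seen.

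Alternatives were size factors by relative log expression (RLE), library totals without further scaling, DESeq2 1.42.0, no filter on low counts, a minimum of 10 counts, edgeR's filterByExpr, a replicate block, a fit of the compared libraries alone, a threshold of 0.10, and leaving out each library in turn. A restriction to circRNAs between annotated exon ends was chosen after seeing the data. With 1 library left out, its group has 1 library, whose spread is assumed to equal that of the other groups.

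The tests were tested on simulated data drawn from the real means and library sizes with the dispersion of the fit (0.239), with 200 circRNAs changed in each of 5 draws. Of circRNAs changed 4-fold, edgeR called 20.2% in A549 (243 tested), 10.2% in MCF-7 (254 tested), 4.66% for the difference between the effects (236 tested), 79.0% for the mean effect (248 tested) and 16.7% between the lines (221 tested). For 8-fold changes the shares were 58.0%, 44.6%, 19.6%, 99.0% and 58.3%. False calls made up 4.46%, 1.52%, 1.75%, 3.13% and 4.05% of the calls. Most true changes of up to 4-fold within a line would thus be missed, and in MCF-7 also most 8-fold changes. For the HIF list in MCF-7, camera called 0 of 40 draws without a change and 40 of 40 draws in which its circRNAs were raised 2-fold. All circRNAs were drawn independently with that 1 dispersion, so these shares hold for such data only. The real replicate pairs differed in spread, with a chi-square per degree of freedom of 1.77 in A549 normoxia and 4.17 in A549 hypoxia. Correlated circRNAs were not simulated, so the shares in the real data may differ. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for annotation and plots. Raw reads and linear RNA were not analysed here.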

Results

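The counts covered 8 libraries, 2 each of A549 in normoxia, A549 in hypoxia, MCF-7 in normoxia and MCF-7 in hypoxia. The A549 normoxia libraries held 13402 and 14426 circRNA counts, the A549 hypoxia libraries 15553 and 13871. The MCF-7 normoxia libraries held 22343 and 26370 counts, the MCF-7 hypoxia libraries 29912 and 35231. At least 1 count was found for 4599 circRNAs in A549 and 7527 in MCF-7, with 2279 in both lines. They came from 3949 host genes, of which 1935 gave a single circRNA. TRIM37 gave 35 circRNAs, BRIP1 29, ASPH 25, BPTF 24 and PICALM 23. The 8591 circRNAs with a count whose ends both lay at exon ends of 1 transcript held a median of 4 exons and 478 nt. Of those placed on the transcript that the annotation marks as canonical, 29.0% began at exon 2.

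A few circRNAs were abundant. In A549, the circRNA over exons 3 to 11 of CYP24A1, which encodes a vitamin D catabolic enzyme (chromosome 20, 54157169 to 54171670, minus strand), stood at 733 ± 54.8 (SD, n = 2) counts per 10000 in normoxia and 635 ± 199 in hypoxia. It took 5.64% to 8.995% of the counts of an A549 library and had 0 counts in each MCF-7 library. A short ASPH circRNA (chromosome 8, 61680968 to 61684188) stood at 442 ± 117 and 303 ± 27.6 in A549, and at 5.21 ± 1.29 and 7.90 ± 0.578 in MCF-7. In MCF-7, the highest were circRNAs of ATXN7, a subunit of a histone acetyltransferase complex, at 195 ± 32.0 in normoxia and 292 ± 39.9 in hypoxia, and of NCOA3, a nuclear receptor coactivator, at 137 ± 16.5 and 215 ± 32.3. Other circRNAs were high in both lines: MAN1A2 lay between 90.7 and 114 in the 4 groups, SPECC1 between 62.5 and 101, and HIPK3 between 29.4 and 64.1.

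The number of circRNAs with at least 1 count was lower in hypoxia in A549 and higher in hypoxia in MCF-7, and a difference between the lines was not tested. In A549, 2934 ± 90.5 (SD, n = 2) circRNAs had at least 1 count in normoxia and 2203 ± 288 in hypoxia. In MCF-7, the means were 4235 ± 57.3 and 5021 ± 578. At 13402 counts per library, the means were 2910 and 2180 in A549 and 3627 and 3873 in MCF-7. These directions depended on the minimum and on the total of counts, and they hold for the circRNAs listed, since a minimum of read support before the tables were made is not excluded. With a minimum of 5 counts the direction in A549 turned, from 660 in normoxia to 894 in hypoxia. At 13402 counts the MCF-7 difference, hypoxia minus normoxia, was -106.9 with a minimum of 2 counts and -57.05 with 5, while that of A549 was -416.05 and 176.55. Of the circRNAs detected in A549, 49.9% had only 1 or 2 counts in normoxia and 30.7% in hypoxia. Within a line the two-sided exact permutation test gave its smallest possible value, p = 0.333 for each of these detection counts. Over both lines the difference in detected circRNAs had an exact p = 1.00 (adjusted over 9 measures, 1.00). With a minimum of 5 counts the mean difference over both lines was 250.25, and with a minimum of 2 after thinning it was -261.47. Each of these had the smallest possible exact permutation p, 0.0556 (adjusted, 0.25).

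**Figure D1:**
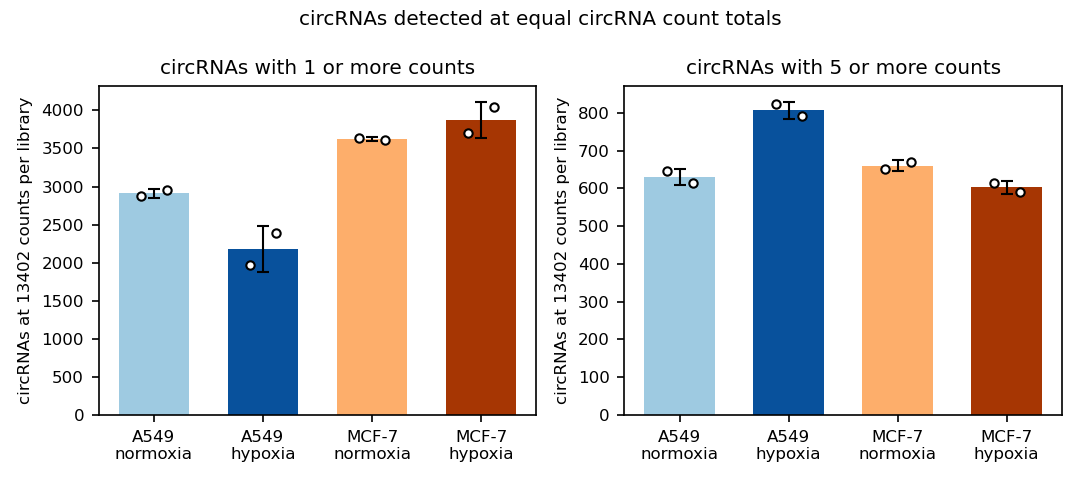
Number of circRNAs with at least 1 count (left) and at least 5 counts (right) per library after thinning to 13402 counts; bars are group means, whiskers the SD and circles the 2 libraries of each group. A549 hypoxia libraries held fewer circRNAs at 1 count (mean 2180 against 2910) and more at 5 counts (806 against 630) than A549 normoxia libraries, while MCF-7 hypoxia libraries held more at 1 count (3873 against 3627) and fewer at 5 counts (603 against 660) than MCF-7 normoxia libraries.

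The first comparison asked which circRNAs respond to low oxygen in A549. A circRNA of PRKAR1B, a regulatory subunit of the cAMP-dependent protein kinase, rose from 1.42 ± 0.0185 (SD, n = 2) to 25.1 ± 5.19 counts per 10000. A circRNA of FAM120A, which encodes an RNA-binding protein, fell from 18.9 ± 1.76 to 2.41 ± 1.06. These were the circRNAs that passed among 694 tested in A549, 1 higher and 1 lower. The PRKAR1B circRNA spans 579256 to 607452 on the minus strand of chromosome 7 and holds coding exons 5 to 9 (451 nt). Its counts were 2 and 2 in normoxia against 52 and 34 in hypoxia, and its log2 fold change was 4.09 ± 0.78 (SE; edgeR adjusted p = 0.003104). It had 0 counts in every MCF-7 library. The FAM120A circRNA spans 93471141 to 93498886 on the plus strand of chromosome 9 and holds coding exons 2 to 5 (556 nt). Its counts were 28 and 25 against 3 and 5, and its log2 fold change was -2.96 ± 0.57 (edgeR adjusted p = 0.003104).

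The circRNAs that follow did not pass over all those tested in A549. Those of BNIP3L, KDM4B and HIF1A belong to the HIF list, which did not pass in A549 (camera adjusted p = 0.778, 7 of 11 above 0). The circRNA of BNIP3L, a mitophagy receptor (chromosome 8, 26391243 to 26408376), had 0 counts in both normoxia libraries and 9 and 8 in hypoxia, at least 4.70-fold higher. The circRNA of the histone demethylase gene KDM4B went from 2.12 ± 1.99 to 9.96 ± 4.68 counts per 10000, with a log2 fold change of 2.18 ± 0.86. For ESYT2 the log2 fold change was 2.09 ± 0.73, with 0 and 8 counts in normoxia against 26 and 16 in hypoxia. Without A549 normoxia replicate 2, which leaves the library with 0 counts, it was 7.76. For TLCD4 the log2 fold change was 2.87 ± 1.04, with 2 and 2 counts against 23 and 14. A circRNA over exons 3 and 4 of HIF1A, the oxygen-regulated subunit of the factor HIF-1, had 6 and 8 counts in normoxia and 0 and 1 in hypoxia, a ratio of 16.9 (95% interval 2.57 to 714). On the lower side, the log2 fold change was -2.45 ± 0.68 for SEMA3C, with 9 and 24 counts in normoxia against 0 and 7 in hypoxia. Without A549 hypoxia replicate 2, which leaves the library with 0 counts, that of SEMA3C was -7.67. CAPRIN1 had 12 and 14 counts against 0 and 3, a ratio of 10.45 (3.202 to 53.94), and ANKHD1 had 5 and 11 against 0 and 1, a ratio of 19.29 (2.997 to 809). UBA2 had 8 and 5 counts against 0 and 0, at least 5.23-fold lower.

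At an unadjusted p under 0.05, 19 circRNAs were higher and 46 lower in A549 hypoxia, against 34.7 expected by chance in all, and the median log2 fold change was -0.19. RLE size factors shifted that median by 0.24 and library totals by 0.19, and the balance became 35 higher and 30 lower, or 32 higher and 34 lower. It was 26 and 21 with DESeq2 and 17 and 22 in a fit of the A549 libraries alone. Left-out libraries also moved it: it was 10 higher and 15 lower without A549 normoxia replicate 1, 20 and 8 without replicate 2, 9 and 39 without A549 hypoxia replicate 1 and 10 and 76 without replicate 2. The A549 hypoxia libraries differed from each other more than any other pair, with a chi-square per degree of freedom of 4.17 against 1.77 to 2.42. Without A549 hypoxia replicate 2 the edgeR count was 10, all lower and with SEMA3C (adjusted p = 0.00229), CAPRIN1 (0.02115) and ANKHD1 (0.0437) among them, and without A549 hypoxia replicate 1 it was 1, a circRNA of FUT8 chosen after its values were seen, with FAM120A at 0.09403 (log2 -2.53). In both of these fits PRKAR1B had too few counts to be tested. Without A549 normoxia replicate 1 or MCF-7 normoxia replicate 1 the count was 0, with PRKAR1B at adjusted p = 0.105 and 0.0774 and FAM120A at 0.0991 and 0.0774. Their log2 fold changes hardly moved in these fits, to 4.11 and 4.11 for PRKAR1B and to -2.86 and -2.93 for FAM120A. Without A549 normoxia replicate 2, PRKAR1B stood at 0.124 (log2 4.08) and ESYT2 passed (0.0388).

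**Figure D2:**
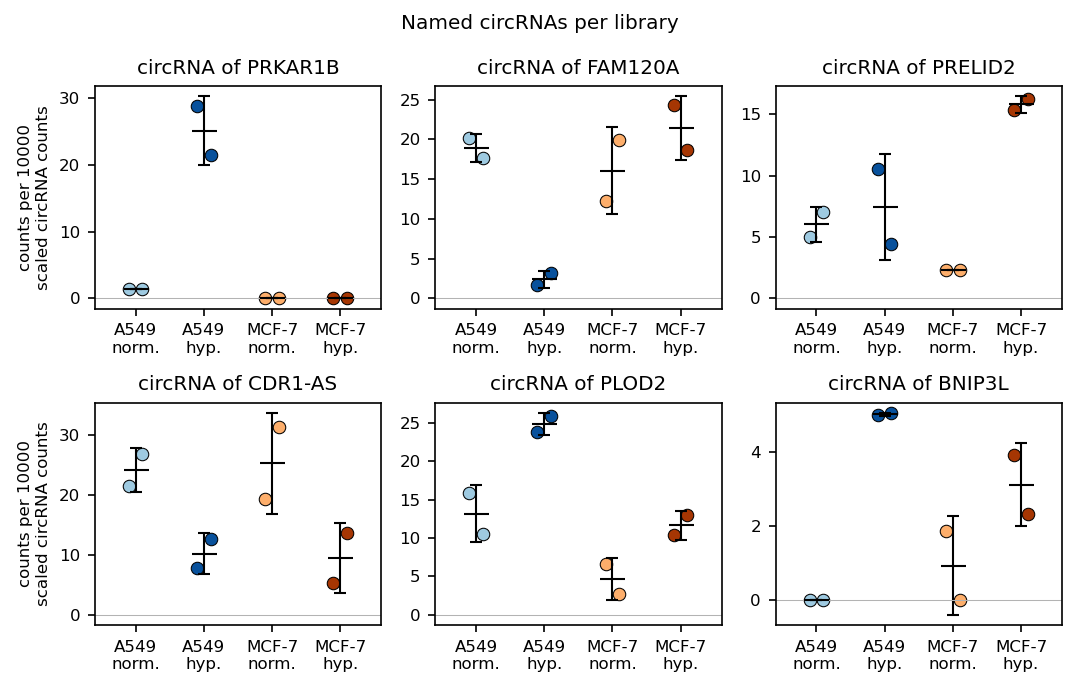
Counts per 10000 scaled circRNA counts of 6 named circRNAs in each library; points are libraries (n = 2 per group), dashes the group mean and whiskers the SD. PRKAR1B rises to 25.1 in A549 hypoxia and is at 0 in MCF-7, and FAM120A falls to 2.41 in A549 hypoxia while its MCF-7 means are 16.1 and 21.4.

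The second comparison asked the same of MCF-7. The smallest unadjusted p belonged to a circRNA of PRELID2, whose product has a domain found in mitochondrial lipid transfer proteins. It stood at 2.35 ± 0.0074 (SD, n = 2) counts per 10000 in normoxia and 15.8 ± 0.669 in hypoxia. As a group, circRNAs of HIF target genes rose in MCF-7: 16 of 17 tested had positive log2 fold changes, with a fitted median of 1.14 (camera adjusted p = 0.000193). With an estimated correlation the adjusted p was 0.0828. Among them was a circRNA of PLOD2, a lysyl hydroxylase that modifies collagen.

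The PRELID2 circRNA (chromosome 5, 145817894 to 145826200, minus strand, exons 2 to 5, 496 nt) had 5 and 6 counts in normoxia and 43 and 49 in hypoxia. Its log2 fold change of 2.72 ± 0.62 (SE) did not pass over the 1527 circRNAs tested (edgeR adjusted p = 0.155). No circRNA did: the count was 0 with edgeR and 0 with DESeq2, with 39 higher and 8 lower at an unadjusted edgeR p under 0.05, against 76.4 expected. That balance was 26 and 12 with RLE size factors, 25 and 15 with library totals and 48 and 43 in a fit of the MCF-7 libraries alone. With DESeq2 it was 18 and 4. It was 57 and 4 without MCF-7 normoxia replicate 1, 52 and 0 without replicate 2, 8 and 4 without MCF-7 hypoxia replicate 1 and 11 and 10 without replicate 2, and 61 and 28 or 61 and 26 without A549 hypoxia replicate 1 or 2. Leaving out A549 hypoxia replicate 1 or 2, which share the estimate of the spread, gave 1 call each, PRELID2 at adjusted p = 0.0118 and 0.00816. After PRELID2, the circRNAs with the smallest unadjusted p on the higher side included SFMBT2, from 11.0 ± 1.57 to 25.8 ± 0.807 counts per 10000 (log2 1.22 ± 0.40). The log2 fold change was 1.40 ± 0.49 for SLTM and 2.14 ± 0.79 for IQGAP1, a scaffold of the actin cytoskeleton. KLHL24 had 0 counts in normoxia and 7 and 11 in hypoxia, at least 4.84-fold higher. The smallest unadjusted p on the lower side belonged to CDR1-AS (ciRS-7), a circRNA with many binding sites for the microRNA miR-7, which the annotation places in LINC00632 (chromosome X, 140783175 to 140784659, plus strand). It went from 25.3 ± 8.44 to 9.49 ± 5.85 counts per 10000 (log2 -1.41 ± 0.44). URI1 followed with 5 and 9 counts against 1 and 0, a ratio of 17.4 (95% interval 2.64 to 734).

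In the HIF list, 0 of 17 circRNAs passed in MCF-7 over all those tested and 0 when adjusted over the list alone. The PLOD2 circRNA over exons 2 and 3 (chromosome 3, 146121112 to 146124229) went from 4.66 ± 2.73 to 11.7 ± 1.85 counts per 10000 (log2 1.34 ± 0.51). It rose within the list of collagen modification and matrix when adjusted over that list alone, where 2 circRNAs were measured, both of PLOD2. The most counted circRNA of the zinc finger gene ZNF292, chosen after its values were seen, had 28 and 17 counts against 40 and 82 (log2 1.08 ± 0.52). In A549, 7 of 11 measured members of the HIF list were positive and the list did not pass (camera adjusted p = 0.778). Adjusted over the list alone, BNIP3L rose and HIF1A fell in A549 (adjusted p = 0.0373 each). The difference between the lines was not detected for this list (camera adjusted p = 0.981 over 9 circRNAs), so the list is not shown to respond differently in the 2 lines. Its median difference was 0.36 although camera ranked it below the other circRNAs.

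**Figure D3:**
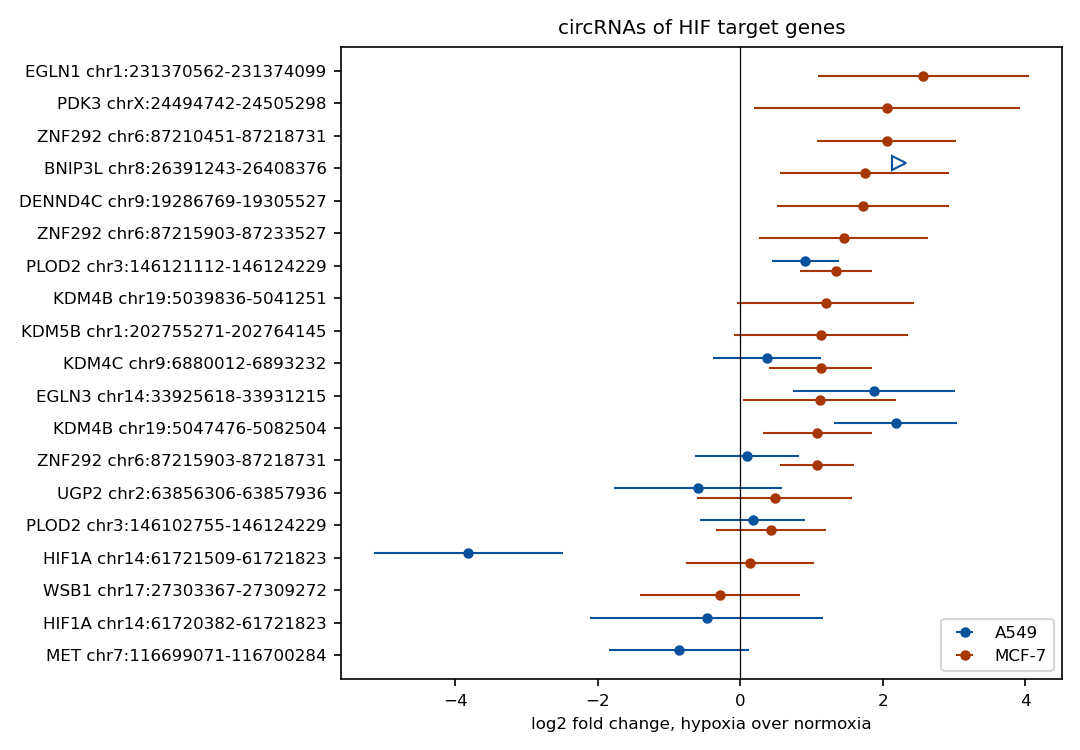
Log2 fold change, hypoxia over normoxia, of each tested circRNA of the HIF list in A549 (blue) and MCF-7 (brown), with approximate SE (n = 2 libraries per group); the open arrowhead is the lower bound for BNIP3L, which had 0 counts in A549 normoxia. In MCF-7 16 of 17 lie above 0, in A549 7 of 11.

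Other lists did not pass with camera in either line under hypoxia. Cell cycle and DNA replication genes had 33 of 52 circRNAs below 0 in MCF-7 (camera adjusted p = 0.157) and 9 of 15 in A549 (0.793). Chromatin modifiers had 31 of 51 above 0 in MCF-7 (camera adjusted p = 0.596), where the rotation test fry, which does not compare a list with other genes, gave an adjusted p of 0.0477. In A549, 10 of 20 were above 0, with a negative median and mean log expression change beside a positive camera direction (0.778). For ubiquitin ligases and proteolysis, 34 of 58 were below 0 in MCF-7 (0.596) and 18 of 29 in A549 (0.778). For splicing factors and RNA-binding proteins, 18 of 35 were below 0 in MCF-7 (1.00), with a positive mean beside a negative camera direction, and 2 of 10 in A549 (0.778). For endoplasmic reticulum stress and protein folding, 10 of 19 were below 0 in MCF-7 (0.818), again with a mean above 0, and 6 of 8 in A549 (0.778). Among abundant circRNA host genes, 68 of 118 were above 0 in MCF-7 (0.818) and 43 of 73 were below 0 in A549 (0.778), FAM120A being the member that passed. The glycolysis and glucose storage list had 2 measured circRNAs in MCF-7, both above 0, and 1 in A549, below 0. The list of A549 lineage and NRF2 pathway genes had 4 of 6 below 0 in A549 (0.796), and the MCF-7 luminal and amplified genes 42 of 73 above 0 in MCF-7 (0.751). In both, the camera direction was opposite in sign to the median and mean log expression change. None of the 41 fibroblast and blood cell genes had a listed circRNA.

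The third comparison tested whether the response differed between the lines, over 470 circRNAs tested in both. The FAM120A circRNA passed: it fell by 2.96 on the log2 scale in A549, while in MCF-7 it stood at 16.1 ± 5.43 (SD, n = 2) and 21.4 ± 3.99 counts per 10000. The difference, MCF-7 minus A549, was 3.37 ± 0.71 (SE; edgeR adjusted p = 0.0173). ANKHD1, SEMA3C and EMC2 had fewer counts in A549 hypoxia than in A549 normoxia, and none of them passed. For SEMA3C the difference was 2.57 ± 0.81 and for EMC2 2.82 ± 0.91. That of SEMA3C moved to 7.81 without A549 hypoxia replicate 2. ANKHD1 had 20 and 17 counts in MCF-7 normoxia and 27 and 37 in hypoxia, beside 5 and 11 against 0 and 1 in A549. On the other side stood ZNF652, at -2.13 ± 0.95, and DOCK1, at -1.75 ± 0.86. The FAM120A difference missed the threshold with RLE size factors (adjusted p = 0.09315), with library totals (0.0751) and with DESeq2 (0.105), at log2 differences of 3.09, 3.09 and 3.12. It also missed it without any 1 of these libraries: A549 normoxia replicate 1 (0.0553) or 2 (0.0585), A549 hypoxia replicate 1 (0.0649), MCF-7 normoxia replicate 1 (0.419) or 2 (0.170), MCF-7 hypoxia replicate 1 (0.296) or 2 (0.0575). The log2 difference in those fits was 2.92 to 3.77. Without A549 hypoxia replicate 2 the count rose from 1 to 10, with SEMA3C at adjusted p = 0.00343 and ANKHD1 at 0.02965 among them, and without A549 hypoxia replicate 1 the count of 1 was the FUT8 circRNA. Over the 470 circRNAs the median difference was 0.37, with 34 higher and 3 lower at an unadjusted edgeR p under 0.05. RLE size factors shifted that median by -0.29, to 0.074, with 23 higher and 10 lower. With library totals the median was 0.076, with 24 and 10. The main scaling thus gave differences that were shifted upwards as a whole, and the FAM120A difference may hold part of this shift.

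Across these 470 circRNAs from 377 host genes, the log2 fold changes of the lines were nearly unrelated (Pearson r = 0.080, Spearman rho = 0.043, across circRNAs, which are not independent replicates). The same sign was found for 50.2%. Of 48 circRNAs at an unadjusted p under 0.05 in A549, 25 had the same sign in MCF-7. The median was 10.62 counts per library, with 2 libraries per group. Noise at such counts lowers the agreement even of a shared response. These values therefore do not show that the lines respond differently.

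The mean effect over both lines asked for a shared response. CDR1-AS was lower in hypoxia in both lines by a similar amount, from 24.2 ± 3.71 to 10.2 ± 3.44 counts per 10000 in A549 and from 25.3 ± 8.44 to 9.49 ± 5.85 in MCF-7 (SD, n = 2). Its mean log2 fold change was -1.33 ± 0.32 (SE), with an edgeR adjusted p = 0.0961 over the 470 circRNAs, and it fell when adjusted over the list alone, as a member of the abundant circRNA host genes. FAM120A also passed over that list alone, but its response differed between the lines, with the lower value in A549 hypoxia and not in MCF-7, so it is not a shared one. circRNAs of HIF target genes rose over both lines, with 7 of 9 above 0 and a fitted median of 0.75 (camera adjusted p = 0.00129; with an estimated correlation, adjusted p = 0.135). BNIP3L, the member with 0 counts in a group, lies above that median also at its bound. Adjusted over the list alone, PLOD2 (log2 1.13 ± 0.35, adjusted p = 0.0112), KDM4B (1.63 ± 0.58, 0.0237) and BNIP3L (0.0112) rose. PLOD2 was at 13.2 ± 3.69 and 24.9 ± 1.46 counts per 10000 in A549. The BNIP3L circRNA had 4 and 0 counts in MCF-7 normoxia and 11 and 7 in hypoxia.

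Over all 470, the edgeR count for the mean effect was 0 and that of DESeq2 was 0, with 18 higher and 26 lower at an unadjusted edgeR p under 0.05, against 23.5 expected. That balance turned to 24 higher and 16 lower with RLE size factors and 21 and 12 with DESeq2, and was 20 and 21 with library totals. It was 8 and 11 without A549 normoxia replicate 1, 22 and 10 without replicate 2, 16 and 50 without A549 hypoxia replicate 2, and 7 and 19 without MCF-7 hypoxia replicate 1. PRELID2 was at 1.52 ± 0.44 (SE), ESYT2 at 1.41 ± 0.47, and PLEKHM1 at -1.94 ± 0.66. ESYT2 moved to 4.26 without A549 normoxia replicate 2. NDUFA10 had 11 and 13 counts against 1 and 2 in A549, a ratio of 9.645 (95% interval 2.929 to 50.04), and 18 and 5 against 3 and 10 in MCF-7. NCOA6 had 6 and 5 counts against 0 and 0 in A549 and 8 and 5 against 1 and 3 in MCF-7. Ubiquitin ligases and proteolysis had 16 of 21 circRNAs below 0 (camera adjusted p = 0.125) and cell cycle and DNA replication 11 of 14 (0.374), the latter at an adjusted p of 0.0268 with fry. Without A549 hypoxia replicate 1 the HIF list had an adjusted p = 0.144 and the count of circRNAs was 1, that of FUT8. Without A549 hypoxia replicate 2 these were 0.155 and 14, with CDR1-AS (adjusted p = 0.00992), PRELID2 (0.0136), ESYT2 (0.0426), PLEKHM1 (0.0438) and NDUFA10 (0.0464) among them. Without A549 normoxia replicate 2 the count was 1, which was ESYT2 (0.0329).

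Counts were also summed over all circRNAs of a host gene. In A549, PRKAR1B rose from 14 and 11 counts to 75 and 55 over 5 circRNAs (log2 2.19 ± 0.48, SE; edgeR adjusted p = 0.0358), as 1 of 771 host genes. This sum includes the called circRNA, with 2 and 2 against 52 and 34 counts, so it is not separate support. In MCF-7, PRELID2 had 23 and 24 against 89 and 131 counts over 9 circRNAs (1.86 ± 0.42; 0.112), and 0 of 1362 host genes passed with edgeR. DESeq2 was not run on the sums. Over both lines, PRELID2 (adjusted p = 0.0679), CDR1-AS, PRKAR1B and KDM4B (0.0796 each) came closest. The A549 count of 1 became 20 without A549 hypoxia replicate 2, and 0 without A549 normoxia replicate 1 or 2, A549 hypoxia replicate 1, MCF-7 normoxia replicate 1 or 2, or MCF-7 hypoxia replicate 1, at log2 fold changes of 1.99 to 2.43 for PRKAR1B. The MCF-7 count of 0 became 1 without A549 hypoxia replicate 1 or 2.

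The last comparison set the lines side by side in normoxia. Among 989 circRNAs, 96 were higher in MCF-7 and 83 higher in A549. Of these, 113 had 0 counts in the normoxia libraries of 1 line, 65 of them among those higher in MCF-7 and 48 among those higher in A549. In the hypoxia libraries, 177 of the 179 kept their direction, 165 of them without overlap between the lines. The circRNAs higher in MCF-7 included those of GFRA1, a receptor of glial cell line-derived neurotrophic factor, of the phosphatase gene PPM1D and of the helicase gene BRIP1. Those higher in A549 included circRNAs of CYP24A1, of ASPH and FAT1, which encode an aspartyl hydroxylase and an atypical cadherin, and of the receptor genes LPAR1 and MET.

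GFRA1 (chromosome 10, 116089741 to 116096764, exons 7 to 9) had 106 and 137 counts in MCF-7 normoxia and 0 in A549, at least 48.6-fold higher (edgeR adjusted p = 1.2e-10). By the same measure, ADAMTS19 was at least 27.8-fold, PPM1D at least 19.99-fold, SULF2 at least 15.4-fold, ISOC1 at least 14.4-fold, CDYL2 at least 12.6-fold and ESRP1, an epithelial splicing regulator, at least 11.6-fold higher. Where both lines had counts, the log2 fold change was 4.57 ± 0.36 (SE) for NCOA3, with 4 and 12 against 315 and 320 counts. It was 4.50 ± 0.34 for ATXN7, 4.08 ± 0.43 for BRIP1, 3.80 ± 0.58 for APPBP2, 3.61 ± 0.63 for TRIM33 and 1.75 ± 0.55 for KMT2C. In the other direction, CYP24A1 had 1074 and 984 counts in A549 and 0 in MCF-7, at least 1144-fold higher (edgeR adjusted p = 2.5e-20). A longer ASPH circRNA (chromosome 8, 61618978 to 61653660) was at least 75.6-fold, FAT1 at least 63.9-fold, MTCL1 at least 42.8-fold, LPAR1 at least 42.3-fold, SLC22A3 and ZBTB20 at least 23.9-fold and MET at least 11.1-fold higher in A549. PSD3 was at -4.15 ± 0.65, the splicing regulator gene PTBP3 at -2.85 ± 0.62, PLOD2 at -1.52 ± 0.53 and ASXL1 at -1.07 ± 0.31, negative values being lower in MCF-7.

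**Figure D4:**
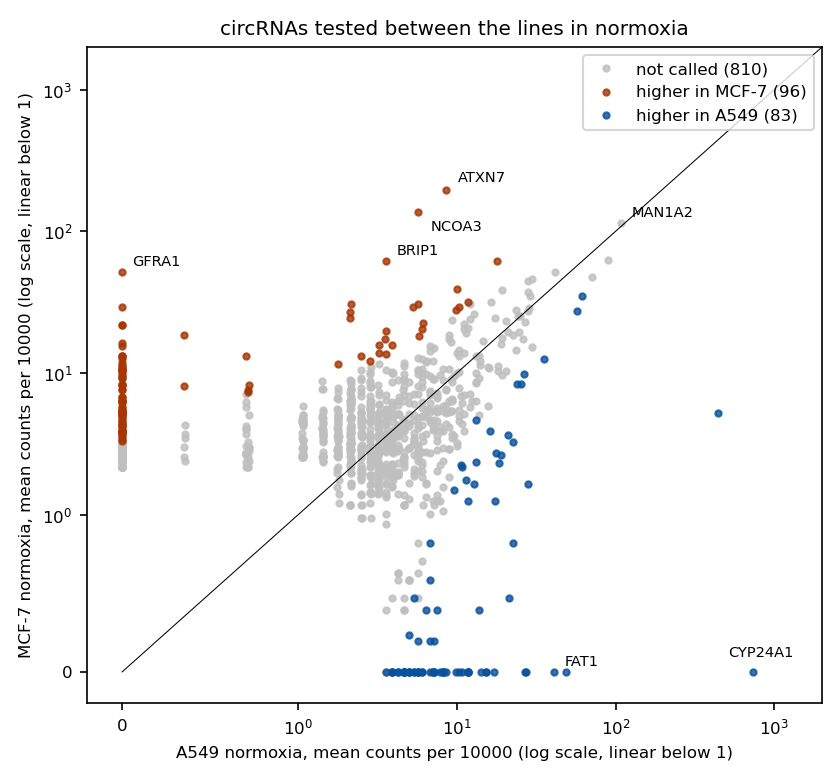
Mean counts per 10000 scaled circRNA counts in A549 normoxia (x) and MCF-7 normoxia (y), n = 2 libraries each, on log axes that are linear below 1; points are tested circRNAs, brown where higher in MCF-7 (96), blue where higher in A549 (83) and grey where not passing. ATXN7, NCOA3 and BRIP1 lie far above the diagonal, and CYP24A1 and FAT1 on the line of 0 in MCF-7.

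The luminal and amplified genes were higher in MCF-7 as a list: 41 of 41 circRNAs had positive log2 fold changes, 23 passed over all tested and 37 when adjusted over the list alone (camera adjusted p = 6.5e-14; with an estimated correlation, adjusted p = 0.0961). Of these, 29 had 0 counts in a group, and with those at their bounds the median log2 fold change was 2.00. These 29 had 0 counts in A549 normoxia and were tested through their MCF-7 counts alone, so the filter fixed their sign. The A549 lineage and NRF2 list had 4 measured circRNAs, all lower in MCF-7, and 2 of them, CYP24A1 and MET, passed. In that list 2 had 0 counts in MCF-7 normoxia, and their sign was fixed in the same way. Among HIF target genes 2 of 9 passed, PLOD2 and MET, both higher in A549 (camera adjusted p = 0.190), and PLOD2 was also the member of 3 matrix circRNAs that passed. Among ubiquitin ligases 6 of 40 passed, all higher in MCF-7, such as TRIM33 and TRIM37 (0.746). The named TRIM37 circRNA had 0 counts in A549 and was at least 8.99-fold higher. TRIM37 alone gave 4 of the circRNAs called higher in MCF-7, so the 6 are not 6 separate genes. The chromatin modifiers had 2 higher in MCF-7, BPTF (at least 8.59-fold) and KMT2C, and ASXL1 lower, of 35 (0.658). Of 19 splicing factor circRNAs 2 were higher and 3 lower (0.746), and PTBP3 alone gave 3 circRNAs called higher in A549. Of 33 cell cycle circRNAs 2 were higher (0.190), and of 9 endoplasmic reticulum circRNAs 1 was higher, XBP1, at least 7.79-fold (0.658). Among 94 circRNAs of abundant hosts 9 were higher and 8 lower (0.746), with a median above 0 beside a negative camera direction, and the single glycolysis circRNA did not pass. The 179 calls became 48 and 46 without A549 normoxia replicate 1 or 2, with 37 higher and 11 lower in MCF-7, or 40 and 6. Without MCF-7 normoxia replicate 1 or 2 they became 35 and 39, with 8 higher and 27 lower, or 9 and 30. Those fits tested 850, 823, 611 and 598 circRNAs, since a circRNA counted in 1 line alone then had too few libraries of that line to be tested. Some named circRNAs missed the threshold when a library was left out, without a change of direction: the log2 fold change in those fits was 1.44 to 1.90 for KMT2C, -1.11 to -2.27 for PLOD2, -0.64 to -1.14 for ASXL1, and -2.06 and -2.00 for PTBP3, and XBP1 and MET kept 0 counts in 1 line. Without A549 normoxia replicate 1 the adjusted p was 0.318 for PLOD2, 0.214 for KMT2C and 0.0979 for XBP1, and without A549 normoxia replicate 2 it was 0.0835, 0.174 and 0.0902, with ASXL1 at 0.2801 and PTBP3 at 0.161. Without MCF-7 normoxia replicate 1 it was 0.0662 for PLOD2, 0.139 for KMT2C, 0.1525 for ASXL1 and 0.07785 for MET, and without MCF-7 normoxia replicate 2 it was 0.313, 0.272, 0.152 and 0.0777, with PTBP3 at 0.0997. KMT2C stood at 0.0659 and 0.0653 without MCF-7 hypoxia replicate 1 or 2. Without a filter on low counts PLOD2 was at 0.295 and ASXL1 at 0.0962, and PTBP3 was at 0.0507 with DESeq2.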

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

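The tests of the replicate spread, of the other FAM120A circRNA, of the dropout without FAM120A and of the host gene sums were chosen only after the result was seen; for the thinning test, the requirement that 95% of the draws fall on 1 side of 0.05 was added after its draws were seen.

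The FAM120A circRNA stood out because its response to hypoxia differed between the lines by a test of the difference itself: the log2 fold change in MCF-7 minus that in A549 was 3.37 (edgeR adjusted p = 0.0173). A fall of the whole locus in A549 is argued against by the circRNA that shares its start and ends at 93476338. That circRNA, chosen after its values were seen, had a log2 fold change of 0.17 ± 0.58 (SE) in A549, which lies 3.13 above that of the called circRNA (SE of the difference 0.811). The remaining FAM120A circRNA tested, from 93470329 to the same end as the called one, had 5 and 8 counts against 0 and 0, at least 5.23-fold lower, so a fall shared by circles with that end is not excluded. A general dropout in the A549 hypoxia libraries could not be decided: of 47 circRNAs with at least 20 counts in both normoxia libraries FAM120A alone had 5 or fewer in both hypoxia libraries (2.13%), the 46 others allow a share of up to 7.71% (exact 95% limit), and 1 of 54 did so in the reverse direction; a response of the line to hypoxia stays open, as untested.

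More circRNAs had lower than higher values in A549 hypoxia, 46 against 19 at an unadjusted p under 0.05, but single libraries decided this: it was 8 against 20 without A549 normoxia replicate 2 and 76 against 10 without A549 hypoxia replicate 2. A linear trend with spliced length or GC content is argued against: the log2 fold changes were nearly unrelated to either (Spearman rho = 0.028 and -0.019, across circRNAs), so that the trend removed was small (SD 0.059 log2), and 47 against 21 were left, a ratio of 2.24. The scaling may account for the excess: under RLE size factors the ratio of falls to rises was 0.857, and DESeq2 gave 21 against 26. Fewer distinct molecules in the A549 hypoxia libraries may contribute, since their replicate spread was 4.17 per degree of freedom against at most 2.42 in the other pairs. A biological fall of many circRNAs in A549 hypoxia stays open and was not tested apart from these.

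circRNAs of HIF target genes rose in MCF-7 under hypoxia (camera adjusted p = 0.000193; adjusted p = 0.0828 with an estimated correlation). Several circRNAs of a few host genes do not account for it, because sums over 15 host genes gave an adjusted p = 0.000319. A linear trend with spliced length or GC content does not either, since it was small (rho = -0.005 and -0.027; SD 0.02 log2) and the list kept an adjusted p = 0.000208 after its removal. The greater depth of the MCF-7 hypoxia libraries stays open: with all libraries thinned to 13402 counts the median adjusted p, 0.0119, met the planned bound of 0.05, but not by more than the spread between draws, which ran from 0.0024 to 0.0958 with 14 of the 18 draws that gave a value under 0.05 and 5 to 10 circRNAs of the list tested in them. A response to hypoxia, the biological reading of the design, stays open beside it.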

How the results depend on the processing

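The restriction to annotated exon ends was chosen after seeing the data. In the totals that follow, a value also kept its side where a circRNA passed in neither fit. Fits in which a circRNA had too few counts to be tested are left out of them. Most named circRNAs were chosen from these same libraries for a large fold change or a small p. A kept direction is therefore no separate support for them. The totals also pool the few calls under hypoxia with many circRNAs that did not pass in the main fit. The PRKAR1B and FAM120A calls each missed the threshold in some fits, as given above. Of 70 pairs of a named circRNA and a comparison, none changed direction: of 1054 recomputed values 994 kept their side of the threshold, 38 lost it and 22 gained it.

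A549 calls (2) became 3 without a filter and with the replicate block, SEMA3C being added, and ranged from 0 to 10 over left-out libraries. The MCF-7 count of 0 became 1 with a minimum of 10 counts, with filterByExpr and with MCF-7 libraries alone, range 0 to 1. The count of 1 for the difference between lines became 0 with RLE, library totals and DESeq2, range 0 to 10. For the mean effect, 0 became 1 with a minimum of 10 counts, filterByExpr, the replicate block and a threshold of 0.10, range 0 to 14. Between lines, 179 became 115 without a filter and 291 with normoxia libraries alone, range 35 to 260. Host gene sums in A549 gave 2 with the block, range 0 to 20, and in MCF-7 1 without a filter and with the block, range 0 to 1.

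Lists called numbered 1 in MCF-7, 1 for the mean and 1 between lines. With an estimated correlation each became 0, and with fry 2, 2 and 8. The estimate was -0.0166 for the HIF list in MCF-7, -0.0627 for the mean and 0.0917 for the luminal list between lines. For the HIF list it lay below the preset 0.01, which argues against correlated members as the reason for the loss of that call. The minimum of 10 counts gave 0 for the mean, and host gene sums 2 between lines. Ranges were 0 to 2 for the mean and 1 to 2 between lines. The HIF list moved to adjusted p = 0.0828 (MCF-7) and 0.1345 (mean) with an estimated correlation, and the luminal list to 0.09605. Over left-out libraries the HIF list for the mean ran from 4.2e-05 to 0.155.

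The difference in detected circRNAs in A549, -731.5, was -414 with a minimum of 2 counts and turned to 233.5 with 5. In MCF-7, 786 became 267 with 5 counts and 245.6 after thinning, and thinning together with a minimum of 2 or 5 counts turned it to -106.9 or -57.05.

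Same-numbered libraries of a line did not deviate together (correlation of deviations 0.022 in A549 and -0.032 in MCF-7), so the block tests a shared number only. Beyond the counts given, it moved SEMA3C in A549 to adjusted p = 0.00832 (0.0114 without a filter; range over its alternatives 0.00229 to 0.809), and CDR1-AS in the mean effect to 0.00999 (0.00923 to 0.682). The difference and the mean need both lines, so no fit of single lines was made for them, and the HIF list had fewer than 5 members at 10 counts in A549 and for the mean. Apart from the estimated correlations of the HIF list, the cause of these changes was not tested, except that fewer circRNAs or libraries enter by construction. Low counts limit all comparisons: the median was 7.38 counts per library in A549 and 4.62 in MCF-7.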

Other observations

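None of the tests in this part was chosen only after the result was seen.

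Host genes of circRNAs that were higher in MCF-7 than in A549 lay together on chromosome 17. In the window from 60 to 70 Mb, 7 of 8 tested host genes had such a circRNA: APPBP2, BPTF, BRIP1, INTS2, PPM1D, TEX2 and USP32. The neighbouring window from 50 to 60 Mb held 4 of 6, RPS6KB1, SPAG9, TRIM37 and VMP1 (permutation p = 0.073). A candidate explanation is the known amplification of this arm in MCF-7, which would raise many neighbouring genes at once. Over windows of 10 Mb, with 74 of 728 host genes called, the highest window score was 6.20 against a 95th percentile of 2.99 in 10000 permutations (p = 1e-04, the smallest they can give). DNA copy number was not measured here, so higher transcription of these genes without more copies stays open. In the opposite direction, the highest window lay on chromosome 9 from 110 to 120 Mb, with LPAR1, PAPPA, PTBP3 and PTGR1 among 6 tested hosts (permutation p = 0.0403, the other of 2 directions tested). There were 0 host genes with circRNAs called in both directions. In the permutations of both directions a host counted as called with at least 1 called circRNA, whatever the number tested. Hosts with more tested circRNAs had more chances of a call, which these permutation p-values do not allow for.

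For the mean hypoxia effect, the 18 splits of the libraries within lines are too few for a share under 0.05 at the real value: 1 split, the real one, reached its 44 circRNAs at an unadjusted p under 0.05, and the highest other reached 43. At an edgeR adjusted p under 0.05 the real split gave 0 circRNAs, and the highest number in another split was 2.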
